A study of Mus musculus with 12 samples.

How the data were processed

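Total RNA was measured in 3 normal lung and 3 lung adenocarcinoma libraries of the Kras G12D model, and small RNA in as many further libraries. Per the labels, RNA for the total RNA libraries was extracted with Trizol, depleted of ribosomal RNA and made into strand-specific libraries with a ScriptSeq kit. The total RNA values are FPKM as deposited, fragments scaled by transcript length and mapped fragments, made with TopHat 1.3.3 and Cuffdiff 1.3.0 on the mouse build mm9, per the submitters' processing notes. The small RNA values are RPM as deposited, reads scaled to a common library total, for 484 hairpins, made with Bowtie 0.12.7 on mm9, per the submitters' processing notes. How reads that match several places were counted is not given. Coordinates are those of the rows in the deposited values.

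In the FPKM values 13 of 5054 genes with a mean of at least 10 FPKM were listed at exactly 0 in 1 or more libraries, Malat1 and Sftpc among them, which can be a failed estimate, and 74 entries name several genes. The median of 1096 olfactory receptor genes, taken as a measure of background, was 0.230, 0.870 and 0.795 FPKM in normal lung replicates 1 to 3 and 0.360, 0.0900 and 0.710 in tumour replicates 1 to 3. In the small RNA values the lowest value was a constant, 1.00 in 4 libraries, 1.30 in normal lung replicate 2 and 3.10 in tumour replicate 3. These last libraries had 1 decimal where the others had 2, and their hairpin copies were counted unlike the others, with a median absolute log2 ratio between copies of 4.89 and 4.28 over 20 pairs, against 0.0364 to 0.145. In 5 libraries 100% of low values lay within 0.1 of a whole multiple of a step. The step gave 58656 reads in normal lung replicate 1, 388542 in normal lung replicate 3, and 136774, 108897 and 485509 in tumour replicates 1 to 3. In normal lung replicate 2 a widest low gap of 0.300 RPM gave at least 3333330 reads. A single read was worth 16.4 RPM in normal lung replicate 1. No count test was run. In normal lung replicate 2 no step was recovered, so whole reads were not available for every library. Copies were also counted unlike the others in that library and in tumour replicate 3.

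Genes with a mean of at least 1 FPKM (12948 of 21882) and hairpins with a mean of at least 10 RPM (293 of 484) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with a trend on the mean, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are tumour minus normal lung on that scale, which understates changes of low genes. The crosses were compared in a fit with tissue as a term. Lists of genes (29) and of microRNAs (18) were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists with at least 3 members tested. An estimated correlation and fry were alternatives. Of the symbols, 21618 were found in the gene name tables. The tests, the lists and the rule for named genes were set before the data were examined.

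Named genes were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose higher group had at least 5 FPKM, leaving out small RNA genes and unnamed models. From each list up to 4 called members were named by size, or the 2 with the highest mean where none was called, and Kras, Xist and Ddx3y in every case. For hairpins the rule took 8 each way with at least 50 RPM, and 3 or 1 per list. For the crosses it took the 4 largest each way. Where fewer than 10 features passed, the 5 with the smallest p each way were named as not passing. Malat1, Sftpc, Sftpa1, Rian and Meg3, the host pairs given and the hairpins of the closing paragraphs other than mir-146b and mir-34a fall outside the rule and were chosen after their values were seen.

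The tests were checked on simulated data. With 200 of 12948 genes changed, the mRNA test recovered 31.3% of those changed by 1 on the log2 scale, 94.0% by 2 and 100% by 4, and 6.25% of its calls were false. With 40 of 293 hairpins changed, the microRNA test recovered 0%, 0% and 15.4%. Alternatives covered the pseudocount (0.1 and 5 FPKM, 0.1 and 10 RPM), filters (none, 5 FPKM, 100 RPM), median-of-ratios and quantile scaling, the trend, a log2 fold change of at least 1, a replicate block, the cross as a term, 1 cross alone and each library left out. Chosen after seeing the data were the removal of failed zeros, subtraction of the olfactory receptor median or its log2 as a term, the highest of hairpin copies, the file format as a term, the 4 small RNA libraries with 2 decimals alone, subtraction of each library's lowest value, leaving libraries out of the list tests and crosses, and the log2 scale for the position of normal lung replicate 1. Summing entries that share a symbol was not run, since 0 symbols had more than 1 entry.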

Results

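The series measured RNA from normal mouse lung and from lung adenocarcinomas of a Kras G12D model, in which mice carry an activated allele of the Ras GTPase gene Kras and tumours are started by viral Cre recombinase given through the nose. Both tissues were sequenced for total RNA and, in separate libraries, for small RNA. Each assay had 3 normal lung and 3 tumour libraries, 12 in all. The mice were offspring of 129S4 males and of females of either 129S4 or MOLF, a strain derived from wild mice. In the total RNA assay 4 libraries came from the cross with MOLF and 2 from 129S4 x 129S4, and in the small RNA assay 2 and 4, with the same make-up in both tissues. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples. Total RNA values were FPKM for 21882 genes, and their sequencing depth is unknown. Small RNA values were RPM, reads scaled to a common library total, for 484 microRNA hairpins. Their spacing put 5 libraries at 58656 to 485509 reads and normal lung replicate 2 at no fewer than 3333330 reads.

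The comparison of tumour with normal lung asks which genes differ in expression between the adenocarcinomas and the tissue they arise in. Genes of macrophages were among the largest rises. Chi3l3, a chitinase-like protein secreted by activated macrophages, had 3990 ± 1823 FPKM in tumours and 237 ± 330 in normal lung (SD, n = 3 each), a log2 fold change of 5.08 ± 1.00 (SE; limma, adjusted p = 0.0131). Its row lies on mm9 chromosome 3 from 105950471 to 105970482, as the file gives it. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 4.37 ± 0.98 (adjusted p = 0.0204), and Ctsk, the cysteine protease cathepsin K, by 3.66 (adjusted p = 0.0118). Of the 20 macrophage markers tested, 14 rose, none fell and 6 did not pass, and 14 rose adjusted over the list alone. The list was higher as a set (camera adjusted p = 2.50e-09, and adjusted p = 0.279 with an estimated correlation). The count was 5 without normal lung replicate 2, 8 without normal lung replicate 3 and 9 without tumour replicate 2. With limma Chi3l3 was not called without normal lung replicate 2 or normal lung replicate 3 (highest adjusted p = 0.0648), Ctsk without normal lung replicate 2 (0.0578), and Gpnmb without those or tumour replicate 1 or 2 (highest 0.0826).

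Other genes with the largest rises were Chi3l4, Ear10, Ear1 and Ear2, at log2 fold changes of 5.13, 4.25, 3.58 and 3.48, which belong to families of similar genes and can share reads with their relatives. Ccl6, a chemokine of myeloid cells, rose from 74.0 ± 71.1 to 831 ± 178 FPKM (log2 fold change 3.89, limma adjusted p = 0.00763). Cxcr1, a chemokine receptor, rose by 4.20 (limma adjusted p = 0.00965). Atp6v0d2, a subunit of the vacuolar proton pump, rose by 3.85, and Marco, a scavenger receptor of alveolar macrophages, by 3.64 (limma adjusted p = 0.0320). Awat1, a wax ester synthase, had 0.0467 FPKM in normal lung and 17.7 in tumours (log2 fold change 3.54). Ccl6, Cxcr1, Ear10 and Ear2 were called whichever library was left out. Atp6v0d2, Awat1 and Ear1 were not called without normal lung replicate 2 (limma adjusted p = 0.0602, 0.0518 and 0.0506), Chi3l4 without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2 (highest 0.0664), and Marco without those or tumour replicate 1 (highest 0.116).

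Markers of the airway and of the gas-exchange surface were lower in tumours. Scgb1a1, the main secreted protein of club cells, changed from 9748 ± 2318 to 1012 ± 742 FPKM (log2 fold change -3.47 ± 0.74, limma adjusted p = 0.0167), and Scgb3a2, a related secretoglobin, by -3.87 (adjusted p = 0.00137). Of 12 club and secretory cell markers tested, 6 fell and none rose (7 fell adjusted over the list alone; camera adjusted p = 0.000209, and adjusted p = 0.279 with an estimated correlation), with Cyp2f2 and Aldh1a1, enzymes of club cells, at -3.37 and -3.03. Ciliated cell markers fell in 16 of 16 cases, also adjusted over the list alone, with Tppp3 at -2.62 and Dynlrb2, a dynein light chain, at -2.03 (camera adjusted p = 7.85e-11, and adjusted p = 0.279 with an estimated correlation). Of 18 alveolar type 1 cell markers, 11 fell and none rose (15 fell adjusted over the list alone; camera adjusted p = 1.22e-06, and adjusted p = 0.315 with an estimated correlation). Cav1, the caveolae protein caveolin 1, changed by -2.64, Cyp2b10 by -2.34 and Rtkn2 by -2.07. The alveolar type 1 count was 3 without normal lung replicate 2, 4 without normal lung replicate 3 and 5 without tumour replicate 1 or tumour replicate 2. Scgb1a1 was not called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2, nor without tumour replicate 1 (highest limma adjusted p = 0.0965).

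Alveolar type 2 cell markers moved the other way. Of 20 tested, 3 rose and none fell, and 10 rose adjusted over the list alone (camera adjusted p = 4.14e-05, and adjusted p = 0.332 with an estimated correlation). Chi3l1 rose by 2.93 and Lyz2, a lysozyme that macrophages also express, by 2.49, while Hc, complement component C5, rose from 63.2 to 256 FPKM. The count was 7 without normal lung replicate 1, 1 without normal lung replicate 2 or normal lung replicate 3, and 5 without tumour replicate 1, and 1 rose and 1 fell without tumour replicate 2. Chi3l1 was called whichever library was left out, while Hc was lost without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2 (highest limma adjusted p = 0.0881) and Lyz2 without those or tumour replicate 1 (highest 0.213). The surfactant gene Sftpc was listed at 0 in tumour replicate 3 and at 9342 and 16762 FPKM in the other tumours, and Sftpa1 was listed at 0 in tumour replicates 1 and 3, values that can be failed estimates. Sftpa1 had 2653, 1004 and 928 FPKM in normal lung and 4336 in tumour replicate 2. Without that library its tumour values are all 0, so the 1 fall called there can rest on these zeros.

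**Figure D1:**
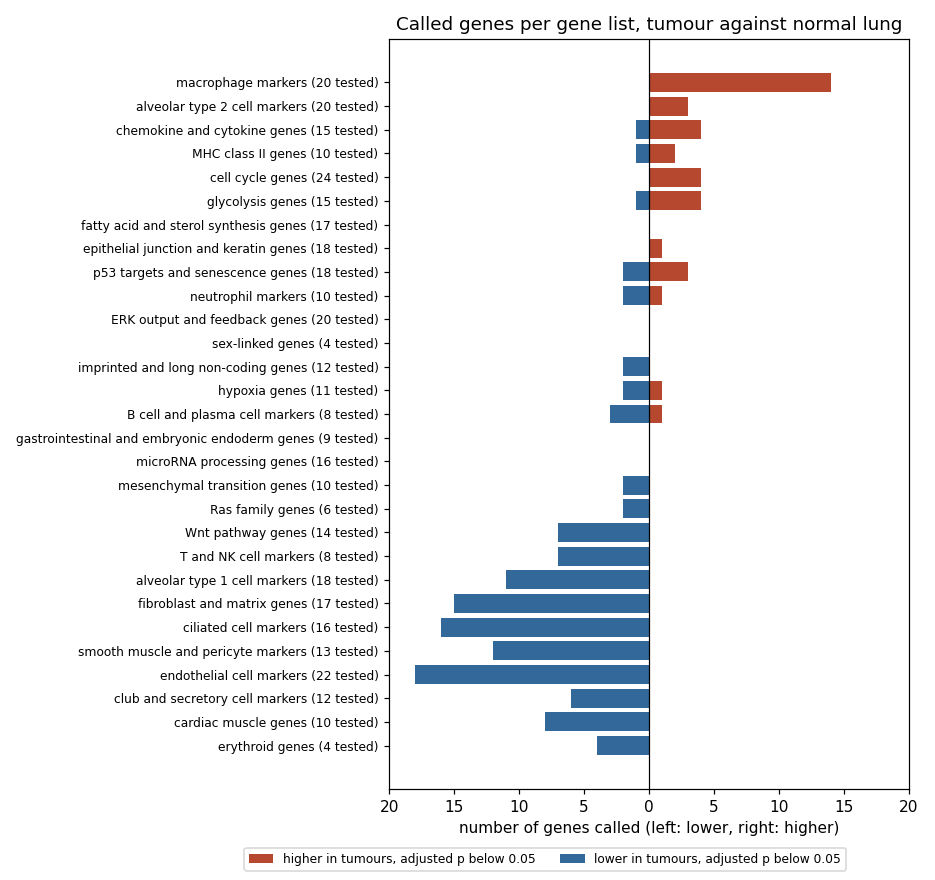
Number of genes called per gene list, as bars to the right for genes higher in tumours and to the left for genes lower in tumours, with the number tested beside each list name. Macrophage markers had 14 genes higher, while endothelial and ciliated cell markers had 18 and 16 genes lower.

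Genes of blood vessels, stroma and muscle were lower in tumours. Tmem100, a membrane protein of endothelial cells, changed by -4.01 (121.8 ± 49.4 against 7.11 ± 4.15 FPKM, limma adjusted p = 0.00252), Ednrb, the endothelin receptor type B, by -3.55, Ramp2 by -3.27 and the endothelial cadherin Cdh5 by -2.83. Of 22 endothelial markers, 18 fell and none rose (20 fell adjusted over the list alone; camera adjusted p = 4.91e-13, and adjusted p = 0.279 with an estimated correlation). Of 17 fibroblast and matrix genes, 15 fell, with Tcf21, a transcription factor of lung mesenchyme, at -2.97, Inmt at -2.75 and Col13a1 at -2.21 (16 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.33e-08, and adjusted p = 0.279 with an estimated correlation). That count was 7 without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2. Of 13 smooth muscle and pericyte markers, 12 fell, with Cnn1, the contractile protein calponin, at -2.77 and Myh11 at -2.38 (12 adjusted over the list alone; camera adjusted p = 1.39e-07, and adjusted p = 0.293 with an estimated correlation). It was 4 without normal lung replicate 2 and 7 without normal lung replicate 3.

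Cardiac muscle genes, which the muscle sleeves of mouse pulmonary veins express, fell in 8 of 10 cases (10 adjusted over the list alone; camera adjusted p = 1.39e-07, and adjusted p = 0.293 with an estimated correlation). Actc1, cardiac actin, changed by -4.16, Myl7 by -4.09, Myl4 by -4.00 and Tnni3 by -3.83. All 4 erythroid genes tested fell, also adjusted over the list alone (camera adjusted p = 2.14e-05, and adjusted p = 0.279 with an estimated correlation). Alas2, the enzyme that starts heme synthesis in red cells, had 33.8 ± 1.22 FPKM in normal lung and 1.36 ± 0.865 in tumours (log2 fold change -3.94, limma adjusted p = 0.000779). The globin rows Hbb-b2 and Hba-a1,Hba-a2 changed by -4.64 and -4.80, and near-identical globin copies make the split of their reads uncertain. Hpgd, which inactivates prostaglandins, changed by -4.00 and Cyp4b1, a cytochrome P450 of lung, by -3.60. In normal lung replicate 1, cardiac muscle genes lay in FPKM at a median of 0.694 of the way from the other normal libraries to the tumours and macrophage markers at 0.147, but on the log2 scale at 0.427 and 0.450.

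**Figure D2:**
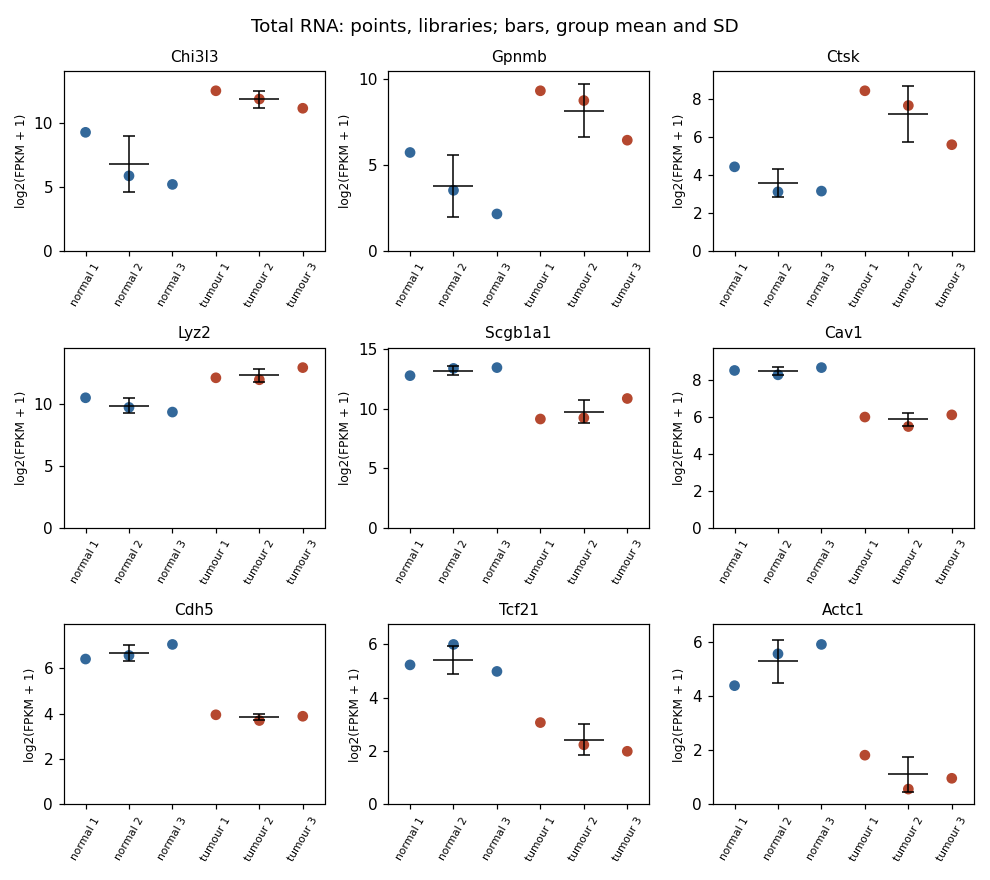
Total RNA levels of 9 genes as log2(FPKM + 1) in the 3 normal lung and 3 tumour libraries, with the mean and SD of each group. Chi3l3, Gpnmb, Ctsk and Lyz2 were higher in each tumour library than in each normal lung library, and the other genes shown were lower.

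Other immune markers were mixed or lower. Of 8 T and NK cell markers tested, 7 fell, also adjusted over the list alone, with Gzma, a granule protease of cytotoxic cells, at -2.09 and Cd3e, a T cell receptor chain, at -1.17 (camera adjusted p = 0.000508, and adjusted p = 0.279 with an estimated correlation). These genes were low, with Cd3e at 3.29 ± 1.02 and 0.883 ± 0.280 FPKM. Of 8 B cell and plasma cell markers, 3 fell, with Ms4a1 at -1.34, and Cd22 rose by 1.29 (the same counts adjusted over the list alone; camera adjusted p = 0.667). Among 10 neutrophil markers, Lcn2 rose by 2.83, Ngp and Csf3r fell, and 7 did not pass (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.924). T and NK calls were 3 without normal lung replicate 2 and 2 without normal lung replicate 3 or tumour replicate 2. With any 1 of these libraries left out, no B cell marker was called lower. Without tumour replicate 1 the set of B cell and plasma cell markers was called lower (camera adjusted p = 0.0261). Neutrophil calls were 0 without normal lung replicate 2 or normal lung replicate 3, and 1 without tumour replicate 1 or tumour replicate 2, and 3 rose without tumour replicate 3. Cd22 was not called without normal lung replicate 2 (limma adjusted p = 0.0522).

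Of 15 chemokine and cytokine genes, 4 rose and 1 fell, with Il1rn, the interleukin 1 receptor antagonist, at 2.55 and Ccl3 at 1.78 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00616, and adjusted p = 0.279 with an estimated correlation). The rises were 1 without normal lung replicate 2 and 7 without tumour replicate 3, and the falls were 0 without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2 and 2 without normal lung replicate 1 or tumour replicate 1. Of 10 MHC class II genes, H2-DMb1 rose by 1.71 and H2-DMb2 by 1.12, while H2-Ob changed by -1.40 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0185, and adjusted p = 0.544 with an estimated correlation). None of these 3 was called without normal lung replicate 2, and only 1 without normal lung replicate 3 or tumour replicate 2. Without tumour replicate 3 the set call of MHC class II genes was lost (camera adjusted p = 0.0642), and 1 rose.

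Proliferation genes were higher in tumours by smaller amounts. Of 24 cell cycle genes tested, 4 rose and none fell, and 14 rose adjusted over the list alone (camera adjusted p = 1.29e-07, and adjusted p = 0.332 with an estimated correlation). Bub1b, a spindle checkpoint kinase, rose by 1.49, Mki67, a marker of dividing cells, by 1.24, Top2a by 1.14 and Mcm3 by 0.84. No cell cycle gene was called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2, whereas 16 were called higher with quantile normalization. Bub1b, Mki67 and Mcm3 were not called without tumour replicate 1 either (limma adjusted p = 0.0657, 0.0539 and 0.0722). Of 18 p53 targets and senescence genes, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0633). Gdf15, a stress-induced cytokine, rose by 2.27 (limma adjusted p = 0.00332) and was called whichever library was left out, with Serpine1 at 1.82 and the cell cycle inhibitor gene Cdkn2a at 1.26. The p53 list had no fall called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2, and 1 rise without normal lung replicate 3. Serpine1 was not called without normal lung replicate 1, normal lung replicate 3 or tumour replicate 1 (highest limma adjusted p = 0.0849), nor Cdkn2a without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2, or tumour replicate 1 (highest 0.116). The set of p53 targets and senescence genes was called higher without normal lung replicate 2 or tumour replicate 2 (camera adjusted p = 0.0493 and 0.0488). Of 15 glycolysis genes, 4 rose, with Hk2 at 1.42 and Pkm2 at 1.23, and Pfkfb3 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00157, and adjusted p = 0.332 with an estimated correlation). No glycolysis gene was called without normal lung replicate 2 or normal lung replicate 3, and 1 without tumour replicate 2, while 2 fell without tumour replicate 3. Hk2 was not called without normal lung replicate 1 either (limma adjusted p = 0.0526).

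Genes downstream of Ras signalling showed no call. None of 20 ERK output and feedback genes passed, also adjusted over the list alone (camera adjusted p = 0.405), and Ccnd1 and Etv5 had log2 fold changes of 0.52 and 0.96 (limma adjusted p = 0.426 and 0.0963). Without tumour replicate 3, 1 was called higher and 4 lower, without normal lung replicate 1, 1 higher and 1 lower, and without tumour replicate 1 Etv5 was called higher (adjusted p = 0.0458). Kras itself had 36.4 ± 3.19 FPKM in normal lung and 28.7 ± 12.1 in tumours (log2 fold change -0.42, limma adjusted p = 0.418). Of 6 Ras family genes, Mras and Rras2 changed by -0.96 and -0.92 (3 fell adjusted over the list alone; camera adjusted p = 0.1198), and none was called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2. Of 14 Wnt pathway genes, 7 fell, with Wnt2, a ligand of lung mesenchyme, at -1.9987, Tcf7 at -1.93 and Axin2 at -1.29 (8 fell adjusted over the list alone; camera adjusted p = 0.000357, and adjusted p = 0.279 with an estimated correlation). The Wnt count was 4 without normal lung replicate 2 or normal lung replicate 3. Of 11 hypoxia genes, Hif1a rose by 0.99, and Epas1 and Vegfa changed by -2.13 and -1.80 (1 and 2 adjusted over the list alone; camera adjusted p = 0.874), none of them called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2. Vegfa was not called without tumour replicate 1 either (limma adjusted p = 0.0802).

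The remaining lists had few calls. Of 18 epithelial junction and keratin genes, Cldn4, a tight junction claudin, alone rose, by 0.99, and none did adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.726 with an estimated correlation). Cldn4 was called only with every library or without normal lung replicate 1 among the leave-outs (highest limma adjusted p = 0.166), and 3 members were called lower without tumour replicate 3. The set call of epithelial junction and keratin genes was lost without normal lung replicate 3 (camera adjusted p = 0.111) or tumour replicate 3 (0.506). Of 10 mesenchymal transition genes, Zeb1, a repressor of epithelial genes, and Tgfb2 changed by -2.06 and -1.28 (3 fell adjusted over the list alone; camera adjusted p = 0.196), and 1 was called without normal lung replicate 2 or normal lung replicate 3. Without tumour replicate 1 the set of mesenchymal transition genes was called lower (camera adjusted p = 0.0261).

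None of 17 fatty acid and sterol synthesis genes passed, also adjusted over the list alone (camera adjusted p = 0.00584, and adjusted p = 0.544 with an estimated correlation), while 1 was called higher without normal lung replicate 1, 2 higher without tumour replicate 1 and 1 lower without tumour replicate 3. None of 9 gastrointestinal and embryonic endoderm genes passed, also adjusted over the list alone (camera adjusted p = 0.874), and their median of -0.17 stood against a set test that pointed up. Of these, 1 was called higher without normal lung replicate 1, and 1 higher and 1 lower without tumour replicate 3. None of 16 microRNA processing genes passed, also adjusted over the list alone (camera adjusted p = 0.134), and 4 were called lower without normal lung replicate 1. Of 12 imprinted and long non-coding genes, Mest and Peg3 changed by -1.24 and -1.17, the 2 calls also adjusted over the list alone (camera adjusted p = 0.844), with a median of -0.10 and a mean of 0.36, while the set test pointed down, and neither was called without normal lung replicate 2, normal lung replicate 3 or tumour replicate 2. The positive mean rests on Malat1, which was listed at 1044 and 2013 FPKM in tumour replicates 1 and 3. It was listed at 0 in tumour replicate 2 and in every normal lung library, values that can be failed estimates. Mest was not called without normal lung replicate 1 or tumour replicate 1 either (limma adjusted p = 0.0605 and 0.0585). None of 4 sex-linked genes passed, also adjusted over the list alone (camera adjusted p = 0.833; median -0.01, mean 0.03, set test up). Ddx3y, a Y-linked helicase gene, had 32.5 ± 7.92 FPKM in normal lung and 33.7 ± 5.86 in tumours, and Xist was too low to test. With median-of-ratios scaling the medians of the B cell, endoderm, hypoxia, imprinted and sex-linked lists were above 0, as were those of the B cell and endoderm lists with quantile normalization.

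Over all genes, 12948 were tested, and 684 rose while 1504 fell in tumours at an adjusted p below 0.05, of which 512 and 1226 changed by at least 1 on the log2 scale. The groups did not overlap for 4592 genes, where chance gives 10%. Of the calls, 68.7% were falls, against 57.9% with quantile normalization and 59.6% with median-of-ratios scaling, which shifted the median log2 fold change of all genes from -0.05 to 0.15. The 2188 calls became 699 without normal lung replicate 2, 830 without normal lung replicate 3, 961 without tumour replicate 2 and 1247 at a mean of at least 5 FPKM. Falls were 90.7% of calls among genes with a mean of 1 to 3 FPKM and 46.9% among genes over 30 FPKM. Normal lung replicate 1 had Spearman correlations across genes, which are not independent replicates, of 0.869 to 0.889 with the tumours, against 0.743 to 0.810 for normal lung replicates 2 and 3. Of the 94 named genes that were called, 42 were called whichever library was left out.

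The small RNA comparison asks which microRNAs differ between the same tissues. Hairpins of the Dlk1-Dio3 imprinted cluster, a group of microRNA genes expressed mainly in embryo, placenta and brain, had higher values in tumours. All 41 tested, of 49 on the list, had positive log2 fold changes, with a median of 4.77. None passed over all 293 hairpins with limma, and 30 passed as higher adjusted over the list alone. Most of the tested members, such as mir-134 at 2.83, had a normal lung mean under the filter of 10 RPM. These were tested only through their tumour values. That largely fixed their direction, so the count, the median and the set test lean on the filter. The normal lung means of mir-541, mir-376a, mir-379, mir-136 and mir-127 lay above it, from 28.05 to 343 RPM. The list was higher as a set (camera adjusted p = 6.83e-27, and adjusted p = 0.376 with an estimated correlation). The hairpin mir-541 had 6649 ± 4963 RPM in tumours and 78.3 ± 40.6 in normal lung (SD, n = 3 each), a log2 fold change of 6.01 (limma adjusted p = 0.0517). The values of mir-376a, mir-379, mir-136 and mir-127 differed by 5.93, 4.84, 5.28 and 4.82 (limma adjusted p = 0.0538, 0.0558, 0.0558 and 0.0571). The list median was 30.02 RPM in tumour replicate 1, 491 in tumour replicate 2 and 436 in tumour replicate 3, against 1.00, 4.20 and 11.1 in the normal libraries. Without tumour replicate 1, 39 of the 41 were called higher, and 23 with the cross as a term.

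**Figure D3:**
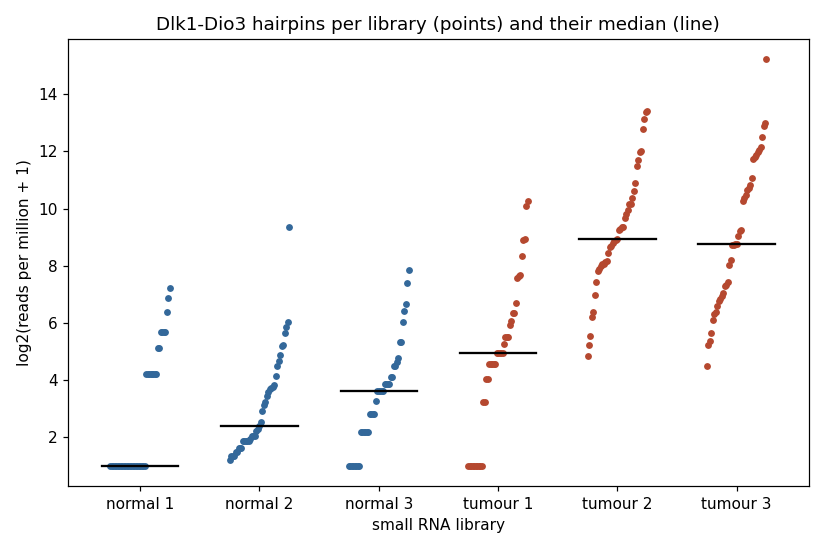
Values of 41 hairpins of the Dlk1-Dio3 cluster in each small RNA library as log2(RPM + 1), with points for hairpins and a line for their median. The medians were 30.02, 491 and 436 RPM in the 3 tumour libraries and at most 11.1 in the normal lung libraries.

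No hairpin passed the threshold with limma, and 64 had an unadjusted p below 0.05; groups did not overlap for 74 hairpins, where chance gives 10%. In simulated data of the same size this test recovered 0% of hairpins changed by 1 or 2 on the log2 scale and 15.4% of those changed by 4. Among named hairpins mir-146b, an inflammation-induced microRNA, had 5277 ± 4640 RPM in tumours and 276 ± 168 in normal lung (log2 fold change 4.07, limma adjusted p = 0.0558). The values of mir-126, which lies in the endothelial gene Egfl7, were 25270 ± 4762 and 136588 ± 39751 RPM (log2 fold change -2.41, limma adjusted p = 0.0598). The smooth muscle microRNA mir-145 differed by -3.09 and the red cell microRNA mir-451 by -3.74 (limma adjusted p = 0.0538 for each), mir-486 by -3.72 (0.0571) and mir-351 by -2.56 (0.0598). With the cross as a term, 26 hairpins were called higher and 8 lower, and within 129S4 x 129S4 alone 42 and 9. Without tumour replicate 1, the 1 tumour library of the cross with MOLF, 46 were called higher and 14 lower. That library had Spearman correlations across hairpins, which are not independent replicates, of 0.796 to 0.882 with normal lung and of 0.703 and 0.779 with the other tumours. Median-of-ratios scaling gave 24 calls and quantile normalization 22. These scalings moved the median log2 fold change of all hairpins from 0.04 to -0.14 and -0.36.

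Smooth muscle microRNAs were lower as a set (6 tested, median -2.73; 3 passed as lower adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.376 with an estimated correlation), with mir-143 at -2.36. The smooth muscle list shares mir-1-1, mir-1-2, mir-133a-1 and mir-133a-2 with the cardiac and skeletal muscle list. Only mir-143 and mir-145 are its own, at -2.36 and -3.09, so the set result is not particular to smooth muscle. Fibroblast microRNAs were also lower as a set (5 tested, median -1.85; 1 passed as lower adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.376 with an estimated correlation), with mir-199b at -2.83. Members also passed adjusted over the list alone among endothelial microRNAs (2 lower of 5; camera adjusted p = 0.103), cardiac and skeletal muscle microRNAs (1 higher and 1 lower of 6; 0.291) and blood and immune cell microRNAs (1 higher and 2 lower of 9; 0.161). The 2 of the endothelial list were mir-126 and mir-486, and the latter differed by -3.72, close to the red cell microRNA mir-451 at -3.74. Its other members mir-139, mir-218-1 and mir-218-2 lay at -0.56, -0.44 and -0.29. No other microRNA list had a member pass, over all hairpins or adjusted over the list alone, and none was called by camera. Among 8 tumour-associated microRNAs mir-21, abundant in many cancers, had 184160 ± 83160 against 47252 ± 11786 RPM (log2 fold change 1.88, limma adjusted p = 0.146). In the miR-34 and miR-449 family mir-34a had 1.52 (limma adjusted p = 0.263) and the median over 4 was -2.37. Hairpin copies count as separate members of a list, and normal lung replicate 2 and tumour replicate 3 counted copies unlike the others. In normal lung replicate 2, let-7c-1 and let-7c-2 had 1145 and 65813 RPM, which limits the medians and set tests of lists with copies. The median was 0.37 for 11 let-7 hairpins, 0.72 for 5 of the miR-200 family, 1.03 for 4 of the miR-29 family and 1.06 for 3 of the miR-183-96-182 cluster. For 13 of the miR-17-92 cluster and paralogs it was 0.27 and the mean 0.15, while the set test pointed down. It was -0.49 for 6 of the miR-30 family, -0.89 for 6 of the miR-181 family, -0.75 for 6 of the miR-99, miR-100 and miR-125 family and -0.98 for 6 of the miR-23, miR-24 and miR-27 clusters. For 7 of the miR-15 and miR-16 family the median was 0.51, the mean -0.37 and the set test pointed down, with mir-15b at 1.40 (limma adjusted p = 0.209). Without tumour replicate 1, 4 smooth muscle, 2 endothelial, 2 cardiac and skeletal muscle, 1 fibroblast and 1 miR-34 and miR-449 family microRNA were called lower, 2 tumour-associated microRNAs higher, and 1 blood and immune cell microRNA higher and 2 lower. The 2 lower calls of the cardiac and skeletal muscle list are hairpins that it shares with the smooth muscle list, and they are counted in both.

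**Figure D4:**
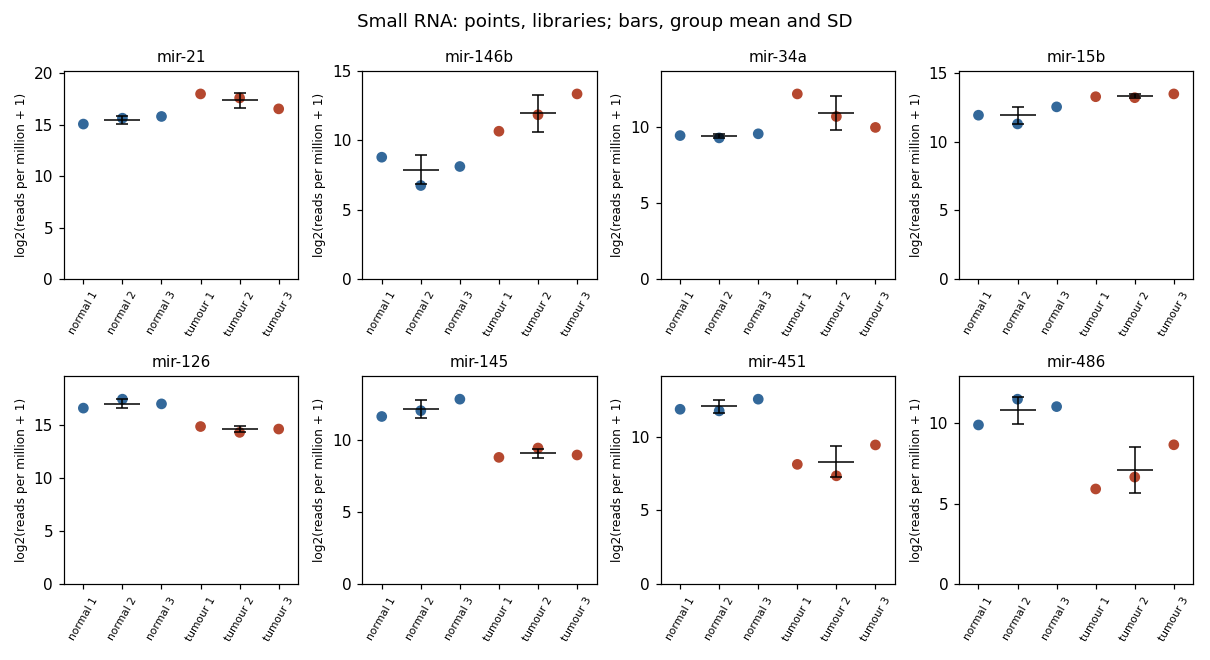
Values of 8 microRNA hairpins as log2(RPM + 1) in each small RNA library, with the mean and SD of each group. The hairpins mir-21, mir-146b, mir-34a and mir-15b had higher values in each tumour library than in each normal lung library, and mir-126, mir-145, mir-451 and mir-486 had lower values, none at an adjusted p below 0.05.

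The crosses allow a comparison of offspring of MOLF mothers with 129S4 x 129S4 mice, fitted beside tissue. Of 12948 genes, 3 were higher and 4 lower in the cross with MOLF. H2-Ea-ps, named as a pseudogene of an MHC class II chain, had 17.8 ± 5.77 FPKM in 4 libraries of the cross with MOLF and 0.140 ± 0.127 in the 2 of 129S4 x 129S4 (log2 fold change 4.00, limma adjusted p = 0.0153). Rpl34-ps1, a ribosomal protein pseudogene, differed by -3.52 (limma adjusted p = 0.0337), and its reads can be shared with Rpl34. Among genes that did not pass, the MHC class I genes H2-Q10 and H2-Bl differed by 1.69 and 2.22 (limma adjusted p = 0.0865 for each), the lipoprotein gene Apob by 4.71 (0.135) and Ang5 by -3.35 (0.0863). The count of 7 was 1 without normal lung replicate 1, tumour replicate 2 or tumour replicate 3, and 0 without tumour replicate 1. Leaving out a library ended both named calls of the cross: H2-Ea-ps was not called without normal lung replicate 1 (limma adjusted p = 0.106), tumour replicate 1 (0.0658) or tumour replicate 3 (0.133), and Rpl34-ps1 was not called without normal lung replicate 1, normal lung replicate 2 or any 1 of the tumour libraries (highest 0.217). Without normal lung replicate 3 or tumour replicate 3 a single library stands for 129S4 x 129S4, and the other libraries supply the spread. No hairpin differed between crosses with limma (smallest adjusted p = 0.231), and 44 of 293 had an unadjusted p below 0.05, with mir-337, mir-92a-2 and mir-154 at -4.20, -4.86 and -4.79. Of these, mir-337 and mir-154 belong to the Dlk1-Dio3 list. In tumours mir-154 had 44.5 RPM in replicate 1, the only one of the cross with MOLF, and 1898 and 4618 in replicates 2 and 3. Among tumours the cross and that library cannot be told apart. A test of whether the tumour effect differed between crosses called 0 genes and 0 hairpins with limma (883 and 32 at an unadjusted p below 0.05), and it rests on 1 library per tissue of 129S4 x 129S4 for genes and of the cross with MOLF for hairpins.

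MicroRNAs within host genes were set beside those genes, since both can come from 1 transcript. The pair of mir-126 and Egfl7 had log2 fold changes of -2.41 and -1.96, and mir-335 and Mest -2.16 and -1.24. The pair of mir-21 and Tmem49 had 1.88 and 0.85, while mir-342 and Evl had -1.06 and 0.98. Of 32 pairs with both members tested, 18 had log2 fold changes of the same sign (56.3%, two-sided exact binomial p = 0.597). The Spearman correlation over pairs, which are not independent replicates, was 0.334 (permutation p = 0.0619). Replicate 2 of each tissue came from the cross with MOLF in total RNA and from 129S4 x 129S4 in small RNA. The libraries of the assays therefore did not all come from the same animals.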

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

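The tests in this part that were chosen only after the result was seen are those of tumour RNA in 1 share, the olfactory receptor background, hairpin copies, depth and neural or muscle RNA, the log2 position of normal lung replicate 1, and the counts of splits. Groups of 3 were too small to look for a single outlying sample, and the test of a tumour effect that differs between the crosses called 0 genes and 0 hairpins with limma (883 and 32 at an unadjusted p below 0.05), with 1 library per tissue in the smaller cross. The patterns here were chosen for their interest.

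Falls were 68.7% of all calls, and 7 of 8 T and NK cell markers fell, though 3 did without normal lung replicate 2 and 2 without normal lung replicate 3 or tumour replicate 2 (list adjusted p = 0.279 with an estimated correlation). With the olfactory receptor median of each library subtracted, falls were 67.87% of calls and 6 of the 8 T and NK cell markers were still called lower, which argues against a background of reads in silent genes as the whole cause. With the log2 of that median as a term, the 2188 calls became 1546, of which 72.7% were falls. Median-of-ratios scaling brought the falls to 59.62%, between the bounds set for either outcome, so part of the excess may come from library scaling. A difference in cell make-up between the tissues stays open and was not tested. The 10 splits of the libraries are too few for a share under 0.05: the real split, the 1 as large, called 2188 genes and the highest other 1.

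In normal lung replicate 1, cardiac muscle genes lay in FPKM at a median of 0.694 of the way from the other normal libraries to the tumours, club cell genes at 0.162 and macrophage genes at 0.147, and on the log2 scale at 0.427, 0.0682 and 0.450, so the contrast with macrophage genes holds in FPKM alone. Over genes called without that library, the median share in FPKM was 0.260 for genes higher and 0.505 for genes lower in tumours, a difference of -0.245 (95% bootstrap interval over genes -0.267 to -0.222). Genes are not independent replicates, so this interval does not measure the spread between libraries. On the log2 scale the median share was 0.422 and 0.361. In FPKM the other lists lay at 0.187 (alveolar type 1), 0.258 (endothelial), 0.339 (ciliated), 0.527 (fibroblast and matrix) and 0.665 (smooth muscle and pericyte). Macrophage, club, type 1 and endothelial genes thus lay closer together than the muscle genes did to them. Mixed RNA adds up in FPKM, where 1 share would place all genes alike. The FPKM values therefore argue against tumour RNA mixed in at 1 share as the whole cause. They cannot exclude such RNA as a part of it. With the olfactory receptor median subtracted its position was 100.7% of that before, which argues against that background. A piece of lung with another cell make-up, alone or beside mixed tumour RNA, stays open and was not tested.

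Dlk1-Dio3 hairpins had higher list medians in all 3 tumour libraries than in any normal library. Most of the tested members passed the filter on low hairpins only through their tumour values, so these medians lean on that filter. Without the libraries that count hairpin copies differently the list median was 4.298. The tested members are not hairpin copies, so copy counting could hardly have moved that median, and this test adds little. The lowest tumour median lay 1.361 (log2) above the highest normal one, although normal lung held the shallowest and the deepest library. The form and bounds of the depth test were set with its values known, and its medians lean on the filter. It therefore cannot decide on depth. The highest of 15 neural and skeletal muscle hairpins lay at a log2 ratio of -3.822 or lower to the list median in tumour replicates 2 and 3, at 27.7 and 29.9 RPM. The form of this test and its bound were set with the values known. A muscle microRNA outside those 15, mir-208b, had 107.9 and 159.7 RPM there. The test therefore cannot decide whether RNA of such tissue was in these 2 libraries. In tumour replicate 1 the highest of the 15 hairpins lay at 4.099, with mir-1-2 at 531 RPM, and members of the 15 reached 634.5 RPM in normal lung. In that library such RNA and a difference between the tissues, which stays open, cannot be told apart. The 10 splits are too few for a share under 0.05: the real split, the 1 as large, gave 4.77 and the highest other 3.732.

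For the other counts the 10 splits are likewise too few for a share under 0.05. No hairpin was called in the real split and 0 in the highest other, so all 10 were as large. The real split called 18 gene lists and the highest other 19, with 3 splits as large. It called 3 microRNA lists and the highest other 6, with 5 splits as large.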

How the results depend on the processing

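Alternatives that left libraries out of list tests and crosses, or used olfactory receptors, hairpin copies or decimals, were chosen after the data were seen. Of the values for named genes 1829 kept direction and side of the threshold, 235 lost the call, 2 gained it and 11 reversed; for hairpins 460 kept it, 131 gained it and 3 reversed; for gene lists 273 kept it, 29 lost, 6 gained and 11 reversed; for microRNA lists 185 kept it, 6 lost and 7 reversed; for the crosses 181 kept it, 9 lost and 8 gained. The 2188 genes called became 1247 at a mean of at least 5 FPKM, where fewer genes are tested, and ranged from 699 to 3040 with a library left out. The 0 hairpins called became 4 with a pseudocount of 10 RPM, 19 with no filter, 7 at 100 RPM, 24 with median-of-ratios scaling, 22 with quantile normalization, 34 with the cross as a term, 51 in 129S4 x 129S4 only, 29 with the highest of hairpin copies, 21 with the file format as a term, 24 with both and 8 in the libraries with 2 decimals, and ranged from 0 to 60 with a library left out. The 7 genes of the cross became 11 with the olfactory receptor median subtracted, and 0 to 9 with a library left out. With an estimated correlation 0 gene lists and 0 microRNA lists were called, and with fry 13 and 0. The cause was not tested.

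With a replicate block 2193 genes and 20 hairpins were called. Whether the replicate numbers pair the libraries cannot be decided, because each tissue has too few libraries. Within each assay, the normal lung and tumour libraries with the same number came from the same cross. Correlations of residuals between tissues at the same number were 0.0209, -0.0394 and 0.313 for genes and 0.253, -0.141 and -0.400 for hairpins. At different numbers they ranged from -0.284 to 0.252 for genes and from -0.323 to 0.514 for hairpins.

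Reversals were all of results not called either way, and the cause was not tested. Adjusted p with fry was 0.710 for neutrophil markers, 0.917 for endoderm genes and 0.897 for the miR-17-92 cluster (0.950 with a replicate block), and 0.868 for sex-linked genes with quantile normalization. With a library left out it ranged from 0.413 to 0.909 for neutrophil, 0.0261 to 0.941 for B cell and plasma cell markers, 0.392 to 0.909 for endoderm, 0.603 to 0.909 for hypoxia genes, 0.421 to 0.978 for imprinted and 0.425 to 0.986 for sex-linked genes, 0.156 to 0.960 for let-7 and 0.513 to 0.933 for miR-17-92. The log2 fold change was -0.0801 for Scd1 in the cross with MOLF only, 0.0540 for Zcchc6 and 0.22 for Xpo5 with median-of-ratios scaling, 0.0221 for Xpo5 with the olfactory receptor median subtracted, -0.0583 for Ddx3y with quantile normalization and -0.14 for let-7c-2 in the libraries with 2 decimals. With a library left out it ranged from -0.0957 to 0.0804 for Xpo5, -0.0720 to 0.247 for Ddx3y, -0.107 to 0.652 for mmu-let-7c-2 and -0.368 to 0.728 for mmu-mir-17. FPKM depth is unknown, and 1 read is 16.4 RPM in the shallowest small RNA library. Host pairs with a microRNA past the threshold gave no value, since none passed.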

Other observations

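The genes and tests in this part were chosen after their values were seen, except Apob, Alb, mir-146b and mir-34a, which the rule named. Long non-coding RNAs of the Dlk1-Dio3 locus were looked at in total RNA. Rian had 2.63, 1.96 and 11.9 FPKM in tumour replicates 1 to 3 and 0.910, 1.28 and 2.20 in normal lung (log2 fold change 1.10, limma adjusted p = 0.190), and Meg3 had a log2 fold change of 0.29 (limma adjusted p = 0.684). The muscle microRNA mir-208b had 393, 107.9 and 159.7 RPM in tumours and 17.4, 14.4 and 11.1 in normal lung (log2 fold change 3.66, limma adjusted p = 0.0698), while mir-133a-1 had 8.25, 1.00 and 5.10 in tumours and 33.8, 309.6 and 205.1 in normal lung (limma adjusted p = 0.0598).

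Apob, a lipoprotein that liver makes, had 90.4, 18.99 and 0.570 FPKM in normal lung replicates 1 to 3 and 50.2, 159.2 and 2.58 in tumour replicates 1 to 3, with the lowest value of each tissue in its 129S4 x 129S4 library (log2 fold change of the cross with MOLF 4.71, limma adjusted p = 0.135). Alb, albumin, had 146.2, 21.9 and 2.40 in normal lung and 0.540, 148.6 and 1.48 in tumours. The liver microRNA mir-122 reached 1053 RPM in a tumour library and 1164 in a normal lung library.

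Related microRNAs went apart. The values of mir-146b were higher in tumours and those of mir-146a lower, at log2 fold changes of 4.07 and -2.18 (limma adjusted p = 0.0558 and 0.104), and mir-34a differed by 1.52 and mir-34c by -2.99 (limma adjusted p = 0.263 and 0.208). None of these passed, and the differences between relatives were not tested. The values of mir-31 were 1379, 4597 and 3962 RPM in tumours and 476, 243 and 928 in normal lung (log2 fold change 2.62, limma adjusted p = 0.0740).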
